A study of Homo sapiens with 21 samples.

How the data were processed

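The series measured gene expression with Illumina bead arrays in peripheral blood mononuclear cells of 7 patients treated with romidepsin, an inhibitor of class I histone deacetylases. Each patient gave a sample labelled 0 h, 4 h and 24 h after treatment, which made 21 samples with 1 array each. Per the labels' protocols, total RNA was extracted with an acid phenol reagent, checked for integrity on a Bioanalyzer, amplified by the array maker's method and labelled with biotin. Per the submitters' processing notes, BeadStudio 3.0 was used, and its role is not given in the sources used here.

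The authors deposited 2 kinds of values, both linear intensity values per probe. The first is a scanner signal for each of 22184 probes on each array, which is not normalised between arrays, since medians and upper quartiles differ from array to array. The second is a value table of 16319 of those probes, in which most columns have nearly the same distribution, with medians from 181 to 191, as quantile normalisation would give. The authors' filter left 5865 probes, or 26.4%, out of the value table. How the authors made the table, whether they subtracted background and how they chose its probes are not given in the sources used here.

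The columns of the value table were compared with the scanner signals by Spearman's rank correlation over probes. For patients 1 to 4 each column ranked its probes exactly as the scanner file with the same label did (rho = 1). For patients 5, 6 and 7 the 2 deposited sources disagree on the time labels. The scanner file labelled 0 h of each of these patients matched the table column labelled 4 h, and the one labelled 4 h matched the column labelled 24 h (rho = 1). The column labelled 0 h and the scanner file labelled 24 h had no such match in these patients, with rho between columns and files of the same label from 0.755 to 0.981. No label settles which source is right. Any result on all 7 patients, from either source, rests on time labels in doubt for 9 samples. These 9 samples therefore entered none of the main comparisons, which rest on the 12 arrays of patients 1 to 4. The plan made before the data were examined was to fit all 21 arrays under the scanner labels. The departure from it was decided from these rank correlations, before any difference between times had been computed, and the planned fit is reported beside the totals of each comparison. No 2 scanner files were identical, and the highest rho between any 2 was 0.981.

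Gene names came from the platform annotation of the value table's probes, with symbols updated through gene identifiers for 14671 of 14680 named probes. None of the named probes carried several symbols, and 1639 probes of the value table had no name and were left out of the gene tests. XIST and Y-linked genes, 14 probes, were left out. Detection p-values, which the plan had used, were not used here. In their place, the 5865 probes outside the value table served as background probes on each array. Signals were corrected with limma's normexp model informed by those probes (offset 16), quantile normalised over the probes of the value table and taken to log2. A probe was called above background on an array where its signal exceeded the 95th percentile of the background probes, and was kept where this held on at least 4 of the 12 arrays. That left 12015 probes. A gene with several kept probes, which was the case for 897 genes, was represented by the probe with the highest mean, and 10958 genes were tested. Where a gene was above background on none of the arrays of a time, its fold is given as a lower bound, set against the lowest signal above background on those arrays.

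Differences between times were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), in a single fit of the 3 time groups without a patient term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, 2-sided, with a threshold of 0.05. A log2 change is a difference of means, and SE is its moderated standard error with n = 4 at each time. The same fit with the patient as a block is given for each count over all genes, and for a list where it moves the count by more than 1.5 times or changes the call. The labels number the patients, and the arrays of a patient did deviate together. Deviations from the time means correlated at 0.28 to 0.761 within a patient (12 pairs, median 0.647) and at -0.46 to 0.201 between patients (36 pairs, median -0.202). The time means are those of the same 4 patients, which by construction pushes the values between patients below 0. The fit without a patient term treats the arrays as independent and keeps these shared deviations in its error. A gene that it does not call is therefore not shown to be unchanged.

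A total of 25 gene lists were fixed before the data were examined: 4 for the MAPK pathway (the ERK arm, the JNK and p38 arms, negative feedback, ERK-inducible genes), 2 for the BCL2 family, and 1 each for the PI3K-AKT pathway, histone deacetylases, genes known to respond to histone deacetylase inhibitors, histones, metallothioneins, heat shock and unfolded protein response, interferon response, NF-kB and cytokine genes, glucocorticoid-inducible genes, clock genes, T cells, NK cells, B cells, monocytes, dendritic cells, neutrophils and their precursors, platelets, erythroid cells and proliferation. Some genes belong to several lists, such as CD163 to the monocyte and glucocorticoid lists and DUSP1 to the feedback and glucocorticoid lists. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists within a comparison. As planned, limma's fry was run beside it and adjusted in the same way. Its directional test asks whether a list's genes moved in a common direction, and its mixed test whether they moved in either. Fry is given for some lists at 4 h against 0 h. With the correlation estimated from the data, none of the camera calls of the main fit held in any comparison. Calls from the other fits, such as those with the block, were not run that way. A list's shift is the mean over its genes of each patient's log2 difference, given with its SD over 4 patients. An exact sign-flip permutation test on 4 patients cannot give a 2-sided p under 0.125, so it cannot pass the threshold.

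The genes named follow a rule fixed in advance. They are the called genes with the largest rises and falls that had the same sign in all 4 patients (8 and 8, or 5 and 5 for 24 h against 4 h; the plan had asked for 6 of 7 patients), the 2 called members with the largest change in each list, and a few fixed genes, some of which are not analysed here. Where 5 or fewer members of a list were called, any not covered by the rule are named too, and these were chosen after their values were seen.

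The steps were tested on simulated data of 10958 genes with 200 changed, with noise drawn independently for each gene and array. At a log2 change of 2 the fit recovered 88% of changed genes for 4 h against 0 h, 89% for 24 h against 0 h and 80% for 24 h against 4 h. At a log2 change of 1 it recovered 42%, 38% and 36%, and it made 5, 4 and 5 false calls. The number of arrays limits the precision. Alternatives covered the patient as a fixed or random block, background correction, scaling to the 75th percentile, the authors' value table, detection filters, averaging of probes, the variance trend, fits of 2 times only, the monocyte marker mean as a covariate and leaving out each patient. Alternatives added after the data were seen were the block on the 21 arrays under the scanner labels, the value table for patients 1 to 4, without patient 7 or with the block, normexp with offset 50, and leaving out each patient within the blocked fit. The 21 arrays without the block, the fit planned at first, became an alternative once the labels were seen to disagree.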

Results

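The data are 21 bead array measurements of gene expression in peripheral blood mononuclear cells of 7 patients, taken at 0 h, 4 h and 24 h of treatment with romidepsin. The series asks how genes of the MAPK pathway differ between these times. Both deposited sources carry the same time labels for the 12 samples of patients 1 to 4, so these samples form 3 groups of 4. For the 9 samples of patients 5, 6 and 7 the scanner signals and the value table disagree on the time, and these samples enter only where a sentence says so. On the 12 arrays used, 71.1% to 78.2% of the value table's probes were above background, with means of 73.3% ± 2.24 at 0 h, 75.9% ± 2.86 at 4 h and 76.3% ± 2.09 at 24 h (SD, n = 4). The lowest of all 21 arrays, none of them among the 12, were under their scanner labels that of patient 7 at 0 h (50.3%) and those of patient 6 at 4 h (60.1%) and 24 h (62.3%). In the value table the first of these is the column of patient 7 at 4 h, and the second that of patient 6 at 24 h.

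**Figure D1:**
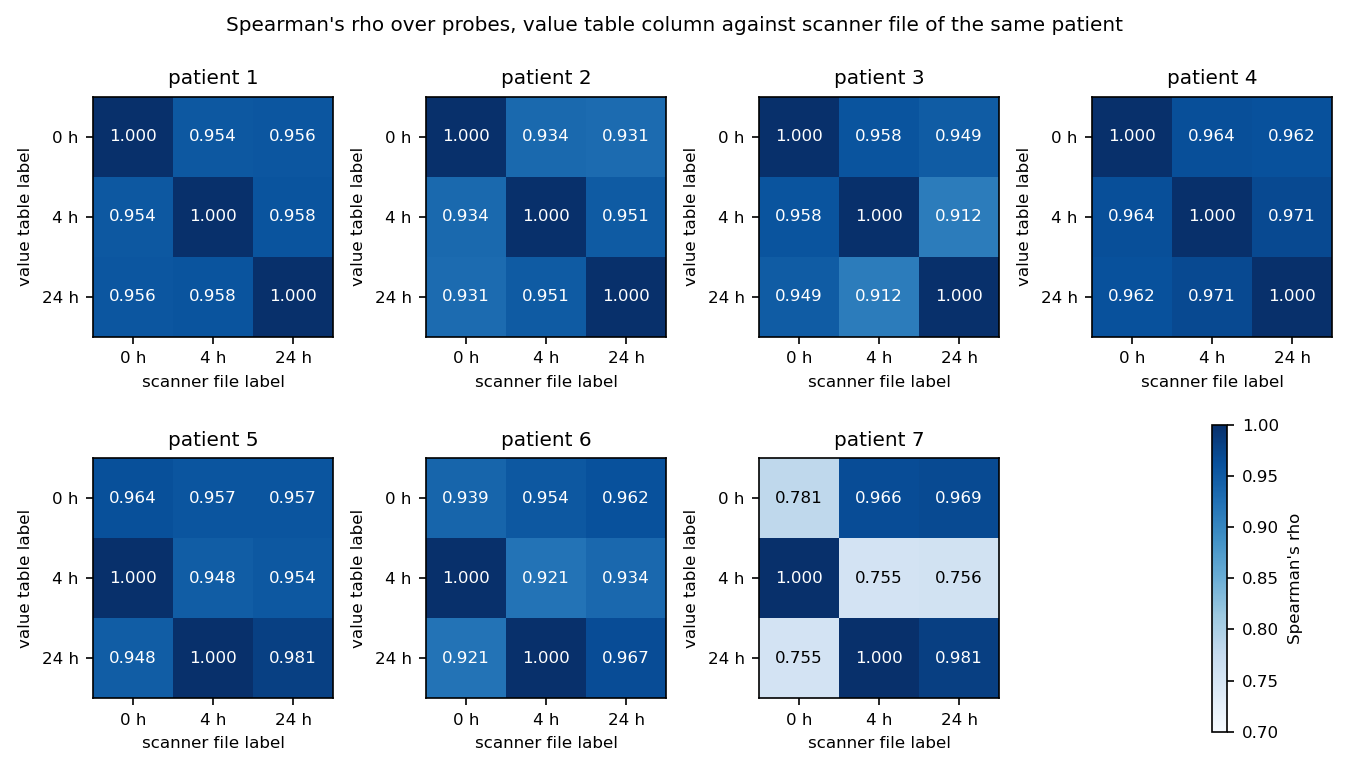
Spearman's rho over probes between each column of the value table (vertical axis, time label in h) and each scanner file (horizontal axis, time label in h) of the same patient, with 1 panel for each of 7 patients. In patients 1 to 4 rho is 1 where both labels are the same; in patients 5 to 7 it is 1 between the scanner files labelled 0 h and 4 h and the columns labelled 4 h and 24 h.

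The comparison of 4 h with 0 h shows what differed in the first hours. HSPA1B, which encodes the heat-inducible chaperone HSP70, rose most, with a mean log2 intensity of 7.79 at 0 h and 10.8 at 4 h (log2 change 3.04, SE 0.32, adjusted p = 0.00262, 8.25-fold). The other largest rises were those of PTTG1, the securin that inhibits separase (2.91), CKS2, a subunit of cyclin-dependent kinases (2.64), ELOVL4, an elongase of very long fatty acids (2.47), TUBB3, a beta tubulin known to respond to histone deacetylase inhibitors (2.34), EPHA1, an ephrin receptor (2.30), MARS2, the mitochondrial methionyl tRNA synthetase (2.30) and DNAAF2, an assembly factor of dynein arms (2.24), with adjusted p from 0.00657 to 0.044. At 0 h ELOVL4, EPHA1 and MARS2 were above background on 3 of 4 arrays. The largest falls were those of MPDU1, a gene of protein glycosylation (-2.05), SLC15A3, a lysosomal transporter (-2.02), the transcription factors ATF5 (-1.76) and KLF11 (-1.74), SLC46A2 (-1.73), FAM20C, a kinase of the secretory pathway (-1.72), NAGPA, a Golgi enzyme that uncovers the sorting tag of lysosomal proteins (-1.71), and CD14, the monocyte co-receptor for endotoxin (-1.71), with adjusted p from 0.00599 to 0.0474. By the rule that chose them, all of these genes moved the same way in 4 of 4 patients.

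Few genes of the MAPK pathway passed the test without the block at 4 h, where 556 of all 10958 genes tested did. Of 36 measured genes of the ERK arm, 0 rose and 1 fell, RPS6KA4, a nuclear kinase that ERK and p38 activate (log2 change -1.10, SE 0.19, adjusted p = 0.0119). The count was also 0 and 1 when adjusted over the list alone, and the list's mean was -0.05 (camera adjusted p = 0.722). Fry's mixed test passed for the ERK arm (adjusted p = 0.00649), while its directional test did not (adjusted p = 0.918). MAPK3, which encodes ERK1, had a log2 change of -0.45 (adjusted p = 0.104, and 0.0325 with the patient as a block) and was lower in 4 of 4 patients. In the value table of 7 patients, with labels in doubt for patients 5 to 7, MAPK3 had -0.26 and did not pass even with the block (adjusted p = 0.408). For MAP2K1 and MAP2K2, which encode the kinases MEK1 and MEK2, the changes were 0.44 (adjusted p = 0.266) and -0.25 (adjusted p = 0.545). Of 43 genes of the JNK and p38 arms 0 passed, over all genes or adjusted over the list alone, with a median of -0.08 and a mean of -0.003 where camera's direction was up (adjusted p = 0.999). Of 25 negative feedback genes 1 rose, over all genes and adjusted over the list alone, which was SPRED2, an inhibitor of Ras signalling. SPRED2 was above background on 0 of 4 arrays at 0 h and was at least 1.46-fold higher at 4 h (adjusted p = 0.0138, and 0.175 after scaling to the 75th percentile). The feedback list's mean was 0.02 and its median -0.05, with camera's direction up (adjusted p = 0.806). Fry's mixed test passed for feedback genes (adjusted p = 0.0186), but not for the JNK and p38 arms (0.34) or ERK-inducible genes (0.473). Its directional test passed for none of these (adjusted p = 0.929 for each). DUSP6, the phosphatase specific for ERK, had a log2 change of -1.13 (adjusted p = 0.208, and 0.0202 with the block). Of 22 ERK-inducible genes 1 fell, over all genes and adjusted over the list alone, the transcription factor KLF6 (-0.72, adjusted p = 0.0346, and -0.75 at a second probe), and the list's mean was -0.24 (camera adjusted p = 0.61). With the block, 2 genes of the ERK arm passed as higher (MKNK2 and ELK1) and 5 as lower (among them RPS6KA4, MAPK3, RASGRP3 and ELK4), 1 of the JNK and p38 arms as higher (STK4), 3 feedback genes as higher (SPRED2, SPRY1 and DUSP14) and 2 as lower (DUSP6 and DUSP8), those outside the naming rule being chosen after their values were seen. SPRY1 was above background on 2 of 4 arrays at 0 h, DUSP6 on 3 of 4 at 4 h, and ELK4 on 3 of 4 at both times.

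Chaperone and histone genes were higher at 4 h. Of 22 heat shock and unfolded protein response genes 5 rose and 0 fell, and 9 rose when adjusted over the list alone. They were HSPA1B, its near copy HSPA1A (2.13), HSPA8 (0.82), HSPD1 (0.94) and DNAJA1 (0.73), the last 3 named after their values were seen. The list's mean was 0.62 ± 0.226 (SD, 4 of 4 patients higher) and passed camera (adjusted p = 8.43e-06), with an adjusted p = 0.377 with an estimated correlation. Heat shock genes passed directional fry too (adjusted p = 0.00673). Of 19 histone genes 2 rose, over all genes and adjusted over the list alone, H2BC5 (2.04, and 1.16 at a second probe) and H2AC11 (1.56, and 0.62 in the value table of 7 patients, adjusted p = 0.0533 with the block). That list's mean was 0.50 ± 0.198 (4 of 4 higher, camera adjusted p = 0.0154, adjusted p = 0.982 with an estimated correlation), and without patient 3 its adjusted p was 0.0889. Histone genes did not pass directional fry (adjusted p = 0.553). Among 9 histone deacetylases HDAC3 (0.86) and HDAC2 (0.82), both class I enzymes, rose, as they did adjusted over the list alone, where 1 more gene passed as lower. The deacetylase list had a mean of 0.27 and was higher in 4 of 4 patients (camera adjusted p = 0.263). Deacetylases passed directional fry (adjusted p = 0.023). Among 17 genes known to respond to histone deacetylase inhibitors only TUBB3 passed, and the list's mean was 0.28 (adjusted p = 0.311). CDKN1A, the cell cycle inhibitor p21 and a known target of such drugs, had a log2 change of -0.19 (adjusted p = 0.894). ABCB1, the drug efflux pump, had one of 1.26 (adjusted p = 0.311). With the block 9 heat shock and 4 histone genes passed as higher, and 2 genes responding to the inhibitors as higher and 1 as lower.

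Monocyte markers were lower at 4 h. Of 17 markers 0 rose and 2 fell, CD14 and MS4A6A (-1.32, adjusted p = 0.0482), and 6 fell when adjusted over the list alone. A second probe of MS4A6A gave -1.07 (unadjusted p = 0.184). The list's mean was -0.70 ± 0.608 and lower in 4 of 4 patients (camera adjusted p = 0.000244, adjusted p = 0.982 with an estimated correlation), and -0.43 without patient 3 (adjusted p = 0.0889). The shifts of single patients ran from -1.48 to -0.0194, so at least 1 patient hardly moved. Monocyte markers did not pass directional fry (adjusted p = 0.432). Under the scanner labels of all 21 arrays, which are in doubt for 9 of them, CD14 had a log2 change of 0.11 and MS4A6A of 0.27. NFKBIA, the NF-kB inhibitor (-1.69), and RELB, an NF-kB subunit (-1.09, named after its value was seen), fell, while TNFAIP6, a hyaluronan-binding protein, rose (1.18), being above background on 2 of 4 arrays at 0 h. These were the 3 called of 21 NF-kB and cytokine genes, whose mean was -0.28 (adjusted p = 0.485). Of 27 interferon response genes 1 fell, IFI35 (-1.05), and the mean was -0.22 (adjusted p = 0.322). Of 12 pro-apoptotic BCL2 family genes 1 fell, BAX (-0.65, adjusted p = 0.0472), and the mean was 0.15 (adjusted p = 0.806). In the value table of 7 patients BAX had -0.22, was higher in 2 of 7 and did not pass, even with the block (adjusted p = 0.197). BCL2L11, the pro-apoptotic protein BIM, had a log2 change of -0.13 (adjusted p = 0.707). Of 23 PI3K-AKT genes 1 rose, PHLPP2, a phosphatase of AKT (0.91, adjusted p = 0.0426), and the mean was 0.03 (adjusted p = 0.904). Of 26 proliferation genes only PTTG1 passed, and the mean was 0.34 (adjusted p = 0.485). Adjusted over the list alone these counts were the same. No member passed in the other lists, over all genes or adjusted over the list alone. Their means were -0.54 for B cells (adjusted p = 0.318, and 0.00458 with the block), 0.25 for T cells (0.485), 0.25 for NK cells (0.722), -0.26 for dendritic cells (0.568), -0.14 for neutrophils (0.806), 0.06 for platelets (0.904), 0.40 for erythroid cells (0.789), -0.12 for glucocorticoid-inducible genes (0.904) and 0.07 for clock genes (0.806). The 5 anti-apoptotic BCL2 genes had a mean of 0.09 and a median of -0.11 (camera up, adjusted p = 0.806), and the 5 metallothioneins a mean of -0.08 with camera's direction up (adjusted p = 0.904). With the block 7 monocyte, 5 B cell and 1 dendritic cell marker and 5 interferon response genes passed as lower, and 1 neutrophil marker and 1 anti-apoptotic gene as higher. In the NF-kB list 1 gene was then higher and 4 were lower. The PI3K-AKT, proliferation and clock lists each had 3 higher and 1 lower, and the glucocorticoid list had 2 higher and 1 lower.

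In all, 293 genes were higher and 263 lower at 4 h of 10958 tested, and 994 and 890 with the patient as a block. With only the arrays of these 2 times 12 and 6 passed, and 3 of the 30 named genes called here still did. All 556 called genes moved the same way in 4 of 4 patients, as 38.6% of all genes did. Without the block the counts changed with every patient: limma called 0 and 0 genes without patient 1 (743 and 666 at an unadjusted p under 0.05), 1 (HSPA1B) and 0 without patient 2 (766 and 707), 133 and 101 without patient 3, and 146 and 107 without patient 4. With the block it called 117 and 69, 233 and 179, 984 and 853, and 759 and 713. In the value table's columns of all 7 patients 116 genes were higher and 104 lower, and 757 and 903 with the block. The labels of 9 of those columns are in doubt. At 4 h the column of patient 7 comes from an array with 50.3% of probes above background. The planned fit of 21 arrays under the scanner labels called 0 and 0 (118 and 66 at an unadjusted p under 0.05), but the labels of 9 of its arrays are in doubt. Under them the 4 h minus 0 h differences of patients 5, 6 and 7 correlated across genes with the mean of patients 1 to 4 at -0.404, -0.549 and 0.0543. A fit with the monocyte marker mean, which itself moved with time, as a covariate called 30 and 27.

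**Figure D2:**
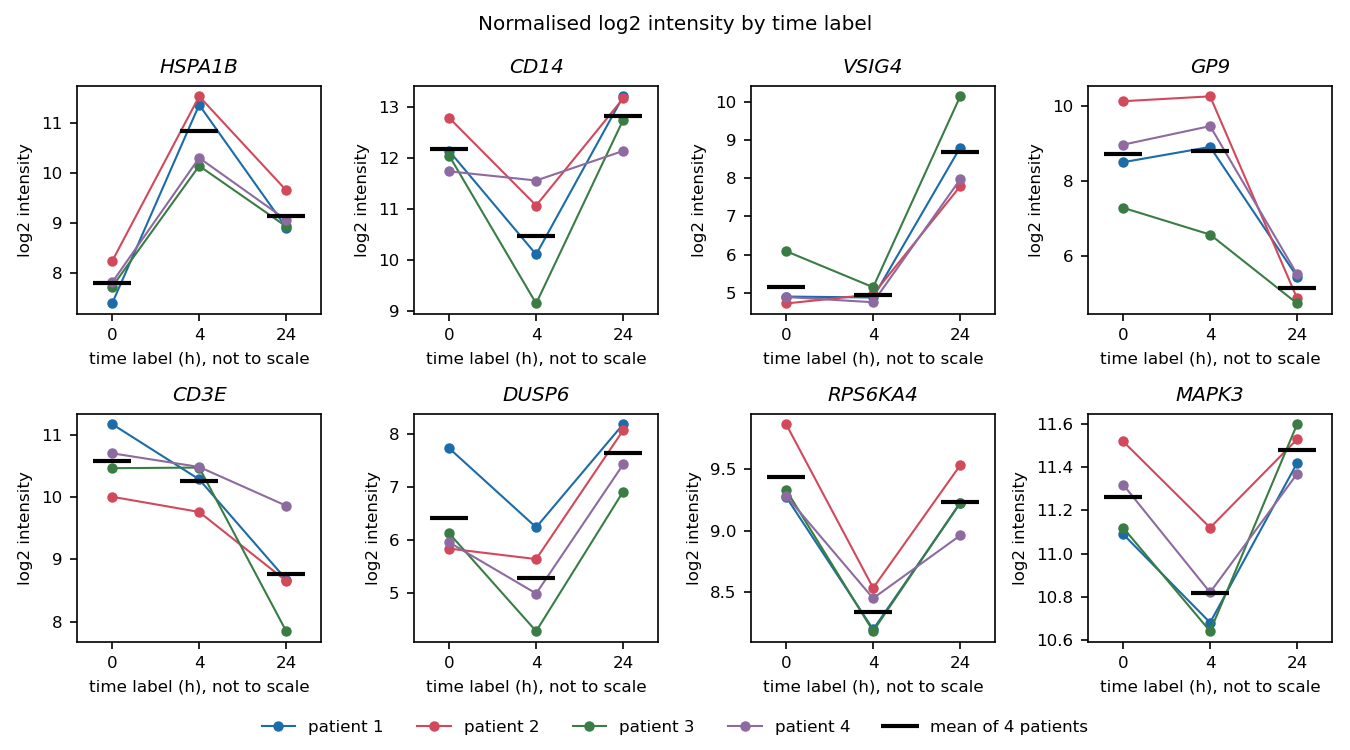
Log2 normalised intensity (vertical axis) at 0 h, 4 h and 24 h (horizontal axis, evenly spaced) for 8 genes in patients 1 to 4, with 1 line for each patient and a black dash at the mean of 4. HSPA1B goes from a mean of 7.79 at 0 h to 10.8 at 4 h, CD14 falls by 1.71 at 4 h, and VSIG4 is 3.52 higher at 24 h than at 0 h.

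The comparison of 24 h with 0 h shows what differed a day after the start. VSIG4, a complement receptor of macrophages, rose most (log2 change 3.52, SE 0.46, adjusted p = 0.0174) and was above background on 3 of 4 arrays at 0 h. The other largest rises were those of CCR2, the chemokine receptor of classical monocytes (2.71), CXCL10, an interferon-induced chemokine (2.48), CYP1B1, a cytochrome P450 (2.36), PID1 (2.35), EMP1 (2.31), ODAD3, a gene of motile cilia (2.29), and CLEC5A, a lectin of myeloid cells (2.27, above background on 3 of 4 arrays at 0 h), with adjusted p from 0.0132 to 0.0412. GP9, a subunit of the platelet receptor for von Willebrand factor, fell most (log2 change -3.60, SE 0.72, adjusted p = 0.0342) and was above background on 3 of 4 arrays at 24 h. CTTN, the actin-binding cortactin (-2.79, 2 of 4 arrays at 24 h), the T cell receptor gene CD3E (-1.84), the T cell adaptors LAT (-1.78) and LIME1 (-1.69), the amino acid transporter SLC38A5 (-1.73), the adhesion gene JAM3 (-1.62) and DMWD (-1.53) followed, with adjusted p from 0.0246 to 0.0437. A second probe of LAT gave -0.38.

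Of all 10958 genes tested 151 passed at 24 h against 0 h, and 649 as higher and 516 as lower with the block. No gene of the MAPK lists passed over all genes, while 12 did with the block. With the block these were, chosen after their values were seen, RRAS and LAMTOR3 (higher) and RASGRP2 (lower) in the ERK arm, MAP4K1, MAPK11 and MAX (lower) in the JNK and p38 arms, DUSP6 and SPRED2 (higher) and DUSP4 and PEBP1 (lower) among feedback genes, and IER3 and KLF4 (higher) among ERK-inducible genes. SPRED2 was above background on 0 of 4 arrays at 0 h. The ERK arm had 0 of 36 genes called and a mean of 0.02 (camera adjusted p = 0.863), and the JNK and p38 arms 0 of 43 and a mean of -0.04 (adjusted p = 0.473), both also with 0 adjusted over the list alone. Negative feedback genes had 0 of 25 called, 1 higher and 1 lower adjusted over the list alone, a mean of 0.001, a median of -0.13 and camera's direction up (adjusted p = 0.863). ERK-inducible genes had 0 of 22 called, 1 higher adjusted over the list alone, and a mean of 0.21 (adjusted p = 0.454, and 0.0396 without patient 4, where the mean was 0.57). Without patient 3 their mean turned to -0.158. MAPK3 had a log2 change of 0.22 (adjusted p = 0.474), MAP2K1 of 0.52 (adjusted p = 0.228), higher in 4 of 4 patients, and MAP2K2 of -0.32 (adjusted p = 0.459). DUSP6 had one of 1.24 (adjusted p = 0.217, and 0.0231 with the block). ABCB1 had one of 1.63 and was higher in 4 of 4 patients (adjusted p = 0.23, and 0.0371 with the block). BCL2L11 (-0.10, adjusted p = 0.77) and CDKN1A (0.77, adjusted p = 0.525) did not pass.

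Myeloid genes were higher at 24 h, and platelet and T cell genes lower. Of 17 monocyte markers 2 rose, S100A12, a calcium-binding alarmin (1.55), and CD36, a scavenger receptor (1.45, and 1.76 at a second probe), and 5 rose when adjusted over the list alone. The monocyte mean was 0.79 ± 0.278, higher in 4 of 4 patients (camera adjusted p = 6.42e-06, adjusted p = 0.636 with an estimated correlation). Of 13 neutrophil and precursor markers 2 rose, the granule protease ELANE (1.81, above background on 3 of 4 arrays at 0 h) and MMP9 (1.6, above background on 1 of 4 arrays at 0 h), and 5 adjusted over the list alone. The neutrophil mean was 0.88 ± 0.346, higher in 4 of 4 (camera adjusted p = 6.42e-06, adjusted p = 0.636 with an estimated correlation). With only genes above background on every array, of which 8273 were tested, the neutrophil list no longer passed camera. Nor did the glucocorticoid-inducible and platelet lists. Like MMP9, the neutrophil markers AZU1 and CXCR1, named after their values were seen, were above background on 1 of 4 arrays at 0 h and 4 of 4 at 24 h. Of 15 glucocorticoid-inducible genes 2 rose, VSIG4 and the adenosine receptor ADORA3 (0.88, above background on 1 of 4 arrays at 0 h), and 5 adjusted over the list alone. The mean was 0.62 ± 0.548 and higher in 3 of 4 (camera adjusted p = 0.0146, adjusted p = 0.636 with an estimated correlation), and 0.41 without patient 3 (adjusted p = 0.115). The 10 members that lymphocytes express too had a mean of 0.109, higher in 2 of 4 patients, and the other 5 one of 1.64. Of 15 platelet markers GP9 and CTTN fell, and 7 fell and 1 rose adjusted over the list alone. The platelet mean was -1.25 ± 0.95, lower in 4 of 4 (camera adjusted p = 0.000226, adjusted p = 0.664 with an estimated correlation), and -0.78 without patient 2 (adjusted p = 0.00457). Of 18 T cell markers CD3E fell, and 2 fell adjusted over the list alone. The T cell mean was -0.72 ± 0.807, lower in 3 of 4 patients (camera adjusted p = 0.0012, adjusted p = 0.636 with an estimated correlation), and -0.40 without patient 3 (adjusted p = 0.0503). With the block 5 monocyte, 7 neutrophil and 5 glucocorticoid-inducible genes passed as higher, 7 T cell markers as lower, and in the platelet list 1 as higher and 7 as lower.

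Interferon response genes also passed as a group at 24 h, with 0 of 27 called and a mean of 0.37 ± 0.135, higher in 4 of 4 patients (camera adjusted p = 0.0469, adjusted p = 0.715 with an estimated correlation). The adjusted p was 0.0801 without patient 1 and 0.0597 without patient 4. Of 21 NF-kB and cytokine genes TNFAIP6 rose (1.91, above background on 2 of 4 arrays at 0 h) and 2 adjusted over the list alone, with a mean of 0.50 (adjusted p = 0.132). Of 19 histone genes H4C8 rose (1.98), with a mean of 0.26 (adjusted p = 0.167). In the other lists 0 members passed over all genes. Means were 0.17 for heat shock genes (adjusted p = 0.379), 0.11 for histone deacetylases (0.458), 0.25 for genes responding to their inhibitors (0.232), 0.39 for metallothioneins (0.189), 0.33 for anti-apoptotic (0.167) and 0.06 for pro-apoptotic BCL2 genes (0.863), -0.06 for PI3K-AKT genes (0.696) and -0.15 for B cells (0.696). The remaining means were -0.38 for clock genes (0.055, and 0.0398 with the block), 0.63 for NK cells (0.0771, and 0.00576), 0.58 for dendritic cells (0.055, and 0.0398), -0.63 for erythroid cells (0.458, and 0.0188) and -0.38 for proliferation genes (0.122, and 0.00179). Adjusted over the list alone, 1 heat shock gene, 1 deacetylase and 3 dendritic cell markers were higher and 1 clock gene and 1 pro-apoptotic BCL2 gene were lower. With the block 5 interferon, 3 NF-kB, 3 heat shock, 1 deacetylase, 1 PI3K-AKT and 2 inhibitor-responsive genes and 2 NK and 4 dendritic cell markers passed as higher, and 1 clock, 1 pro-apoptotic and 2 proliferation genes as lower.

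In all, 118 genes were higher and 33 lower at 24 h than at 0 h, and 649 and 516 with the patient as a block. After scaling to the 75th percentile they were 59 and 24, and 7 of the 23 named genes called here no longer passed (CYP1B1, CLEC5A, JAM3, H4C8, ADORA3, CD36 and MMP9). All 151 called genes moved the same way in 4 of 4 patients, as 35.2% of all genes did. Here too limma called 0 and 0 genes without patient 1 (667 and 482 at an unadjusted p under 0.05) and without patient 2 (799 and 539), 17 and 2 without patient 3, the latter being GP9 and EXOSC6, and 29 and 8 without patient 4. With the block it called 8 and 0 without patient 1 (1108 and 966 at an unadjusted p under 0.05), 110 and 48 without patient 2, 728 and 476 without patient 3, and 316 and 208 without patient 4. The value table's columns of 7 patients, 9 of them with labels in doubt, gave 14 higher and 1 lower, CTTN, and 439 and 278 with the block. The planned fit of 21 arrays, 9 of them with time labels in doubt, called 0 and 0 (402 and 231 at an unadjusted p under 0.05). So did a fit with the monocyte marker mean, which itself moved with time, as a covariate (809 and 598).

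The comparison of 24 h with 4 h, the later part of the course, had the largest count. CYP1B1 (log2 change 3.88, adjusted p = 0.00429), VSIG4 (3.74), the secreted ribonuclease RNASE1 (3.25), CCR2 (3.04) and SLC46A2 (2.80) rose most, with adjusted p up to 0.0314. GP9 (-3.68, above background on 3 of 4 arrays at 24 h), CKS2 (-2.73), the platelet tubulin TUBB1 (-2.64), CTTN (-2.59, 2 of 4 arrays at 24 h) and SH3BGRL2 (-2.39) fell most, with adjusted p from 0.0124 to 0.0462.

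More MAPK genes passed here than against 0 h, and in both directions. The same held for all 10958 genes tested, of which 768 passed here, 556 at 4 h against 0 h and 151 at 24 h against 0 h. In the ERK arm 3 of 36 genes rose, RRAS, a small GTPase related to Ras (1.48), RPS6KA4 (0.89, named after its value was seen) and MAPK3 (0.67, adjusted p = 0.0235, but 0.135 in the value table of 7 patients with the block), and 1 fell, MKNK2, a kinase of translation factor eIF4E (-1.28). Adjusted over the list alone 4 rose and 1 fell, and the list's mean was 0.07 (camera adjusted p = 0.397). MAP2K1 had a log2 change of 0.08 and MAP2K2 of -0.07. Of 43 genes of the JNK and p38 arms 2 fell, the stress sensor GADD45A (-1.06) and MAP3K14, the NF-kB-inducing kinase (-1.02), and 1 adjusted over the list alone, with a mean of -0.04 (adjusted p = 0.544). In the value table of 7 patients with the block neither GADD45A (adjusted p = 0.0994) nor MAP3K14 (adjusted p = 0.0997) passed. Of 25 feedback genes DUSP6 rose (2.36, SE 0.50, adjusted p = 0.0194, above background on 3 of 4 arrays at 4 h), and 1 rose and 2 fell adjusted over the list alone, with a mean of -0.02 (adjusted p = 0.62). Of 22 ERK-inducible genes 0 passed in limma, over all genes or adjusted over the list alone. Their mean was 0.45 ± 0.515 and higher in 3 of 4 patients (camera adjusted p = 0.0719). It passed without patient 1 (0.54, adjusted p = 0.0239), without patient 4 (0.62, adjusted p = 0.0217) and in the value table of 7 patients (0.39, adjusted p = 0.0321). Without patient 3 the mean was lower, at 0.222. With the block the genes higher and lower were 5 and 2 in the ERK arm, 1 and 6 in the JNK and p38 arms, 4 and 4 among feedback genes, and 2 (IER3 and KLF6) and 1 (CCND1) among ERK-inducible genes. Among those new in the ERK arm were RASGRP4 (higher) and HRAS (lower), and in the JNK and p38 arms MAPKAPK3 (higher) and MAP4K1, MAPK11, STK4 and MAX (lower). New among feedback genes were DUSP1, DUSP3 and SPRED1 (higher) and DUSP14, DUSP16, PTPN7 and PEBP1 (lower), all chosen after their values were seen.

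Monocyte markers rose together from 4 h to 24 h, with 12 of 17 higher, 0 lower and 17 higher adjusted over the list alone. CD14 (2.35), S100A12 (2.24), MS4A6A (2.08, and 2.19 at a second probe) and CSF1R, the receptor for macrophage colony-stimulating factor (2.0), were among them. The list's mean was 1.48 ± 0.867 and higher in 4 of 4 patients (camera adjusted p = 2.23e-13, adjusted p = 0.294 with an estimated correlation). Beside it, 3 of 11 dendritic cell markers rose, CLEC10A (2.23, but 0.88 at a second probe), CD1D (2.02) and FCER1A (1.74, named after its value was seen), with a mean of 0.84 ± 0.595. Of 13 neutrophil and precursor markers ELANE (1.87, above background on 3 of 4 arrays at 4 h), MMP9 (1.68, 1 of 4 arrays at 4 h) and AZU1 (1.09, 2 of 4 arrays at 4 h, named after its value was seen) rose, and 10 adjusted over the list alone and 9 with the block, with a mean of 1.02 ± 0.588. Camera's adjusted p was 0.00702 for dendritic cells and 2.19e-05 for neutrophils, and both had an adjusted p = 0.294 with an estimated correlation.

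The means of NF-kB and cytokine, glucocorticoid-inducible and interferon response genes were higher with them, though not all members were. Of 21 NF-kB and cytokine genes 3 rose, the chemokine CCL2 (2.31), the interleukin-1 antagonist IL1RN (2.31, and 1.41 at a second probe) and NFKBIA (1.5, named after its value was seen), with a mean of 0.78 ± 0.853, higher in 3 of 4 (camera adjusted p = 0.0066, adjusted p = 0.413 with an estimated correlation), and 0.41 without patient 3 (adjusted p = 0.0656). Of 15 glucocorticoid-inducible genes 4 rose and 1 fell, and 8 and 2 adjusted over the list alone. They were VSIG4, the transcription factor CEBPD (2.24), CD163, a scavenger receptor that is also a monocyte marker (1.80), ADORA3 (0.61, above background on 3 of 4 arrays at 4 h) and, lower, the cytokine inhibitor SOCS1 (-1.37), the last 3 named after their values were seen. The mean was 0.74 ± 0.472, higher in 4 of 4 (camera adjusted p = 0.0131, adjusted p = 0.294 with an estimated correlation). With only genes above background on every array, the glucocorticoid-inducible list no longer passed camera. Of 27 interferon response genes OAS1, an RNA sensor, rose (1.70, and 1.45 and 0.43 at other probes, the latter with an unadjusted p = 0.163), with a mean of 0.59 ± 0.406, higher in 4 of 4 (camera adjusted p = 0.000288, adjusted p = 0.541 with an estimated correlation). With the block 5 NF-kB genes passed as higher, 8 glucocorticoid-inducible genes as higher and 3 as lower, and 11 interferon response genes as higher and 1 as lower. The 3 lower glucocorticoid-inducible genes were SOCS1, FKBP5 and PER1, the last above background on 3 of 4 arrays at 24 h. FKBP5 and PER1 were named after their values were seen.

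Heat shock, T cell, platelet, proliferation and clock genes were lower at 24 h than at 4 h. Of 22 heat shock genes 5 fell, HSPA1B (-1.70), the co-chaperone BAG3 (-1.39), the stress transcription factor DDIT3 (-1.29), HSPA8 (-0.77) and HSP90AB1 (-0.68), while HSPA6, another inducible HSP70, rose (2.03). BAG3, DDIT3, HSPA8 and HSP90AB1 were named after their values were seen. Adjusted over the list alone 6 fell and 1 rose, and the mean was -0.45 ± 0.132, lower in 4 of 4 (camera adjusted p = 0.000111, adjusted p = 0.294 with an estimated correlation). Of 18 T cell markers CD27 (-1.91) and CD3E (-1.5) fell, and 8 adjusted over the list alone, with a mean of -0.97 ± 0.709, lower in 4 of 4 (camera adjusted p = 4.32e-05, adjusted p = 0.294 with an estimated correlation). Of 15 platelet markers 5 fell, GP9, TUBB1, CTTN, GP1BB (-2.35) and TREML1 (-1.5, above background on 3 of 4 arrays at 24 h), the last 2 named after their values were seen, and 7 fell and 1 rose adjusted over the list alone. The platelet mean was -1.30 ± 1.25, lower in 3 of 4 (camera adjusted p = 0.000332, adjusted p = 0.594 with an estimated correlation), and -0.75 without patient 2 (adjusted p = 0.0184). Of 26 proliferation genes PTTG1 fell (-2.39), with a mean of -0.71 ± 0.38, lower in 4 of 4 (camera adjusted p = 0.00702, adjusted p = 0.691 with an estimated correlation). Of 14 clock genes DBP (-1.53) and CRY2 (-0.97) fell, and 3 adjusted over the list alone, with a mean of -0.45 ± 0.282, lower in 4 of 4 (camera adjusted p = 0.0277, adjusted p = 0.294 with an estimated correlation, and 0.107 without patient 2). With the block 9 T cell, 8 platelet and 9 proliferation genes passed as lower, and 1 platelet marker as higher. The platelet and clock lists no longer passed camera with only genes above background on every array.

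Other lists did not pass from 4 h to 24 h, though some of their genes did. HDAC3 fell (-0.82) while the deacetylase mean was -0.15 (adjusted p = 0.309), TUBB3 fell (-1.75) with a mean of -0.03 for genes responding to their inhibitors (0.557), and BID, a pro-apoptotic BCL2 protein, rose (0.97) with a mean of -0.08 (0.747). Among histones H2BC5 fell (-1.61, and -0.78 at a second probe, unadjusted p = 0.109) and H4C8 rose (1.59), with a mean of -0.24 (0.226). Means were 0.24 for anti-apoptotic BCL2 genes (0.34), -0.09 for PI3K-AKT genes (0.557), 0.46 for metallothioneins (0.301), 0.38 for NK cells (0.309), 0.39 for B cells (0.309, and 0.0154 with the block) and -1.03 for erythroid cells (0.237, and 0.000191 with the block). For every list of this comparison without a count adjusted over the list alone, that count was the same as over all genes. With the block 2 inhibitor-responsive genes were higher and 4 lower, 1 histone gene was higher and 2 lower, 1 pro-apoptotic gene was higher and 1 lower, 1 PI3K-AKT gene was higher and 2 lower, 1 anti-apoptotic gene and 1 B cell marker were higher, and 5 erythroid markers were lower. BCL2L11 had a log2 change of 0.02, CDKN1A of 0.96 (adjusted p = 0.355) and ABCB1 of 0.37.

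In all, 484 genes were higher and 284 lower at 24 h than at 4 h, and 1246 and 1133 with the patient as a block. Without the block 767 of the 768 called genes moved the same way in 4 of 4 patients, as 43.7% of all genes did. Without patient 1 limma called 0 and 0 (1015 and 803 at an unadjusted p under 0.05), without patient 2 it called 78 and 20, and without patient 3 it called 20 and 5, the latter being GP9, GP6, JPT1, KPNA2 and ODC1, and without patient 4 it called 495 and 273. With the block it called 336 and 253, 753 and 550, 627 and 545, and 1161 and 992 in these fits. The value table's columns of 7 patients, 9 of them with labels in doubt, gave 184 and 94, and 1148 and 906 with the block. The planned fit of 21 arrays, 9 of them with time labels in doubt, called 0 and 0 (81 and 104 at an unadjusted p under 0.05). So did a fit with the monocyte marker mean, which itself moved with time, as a covariate (405 and 369).

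**Figure D3:**
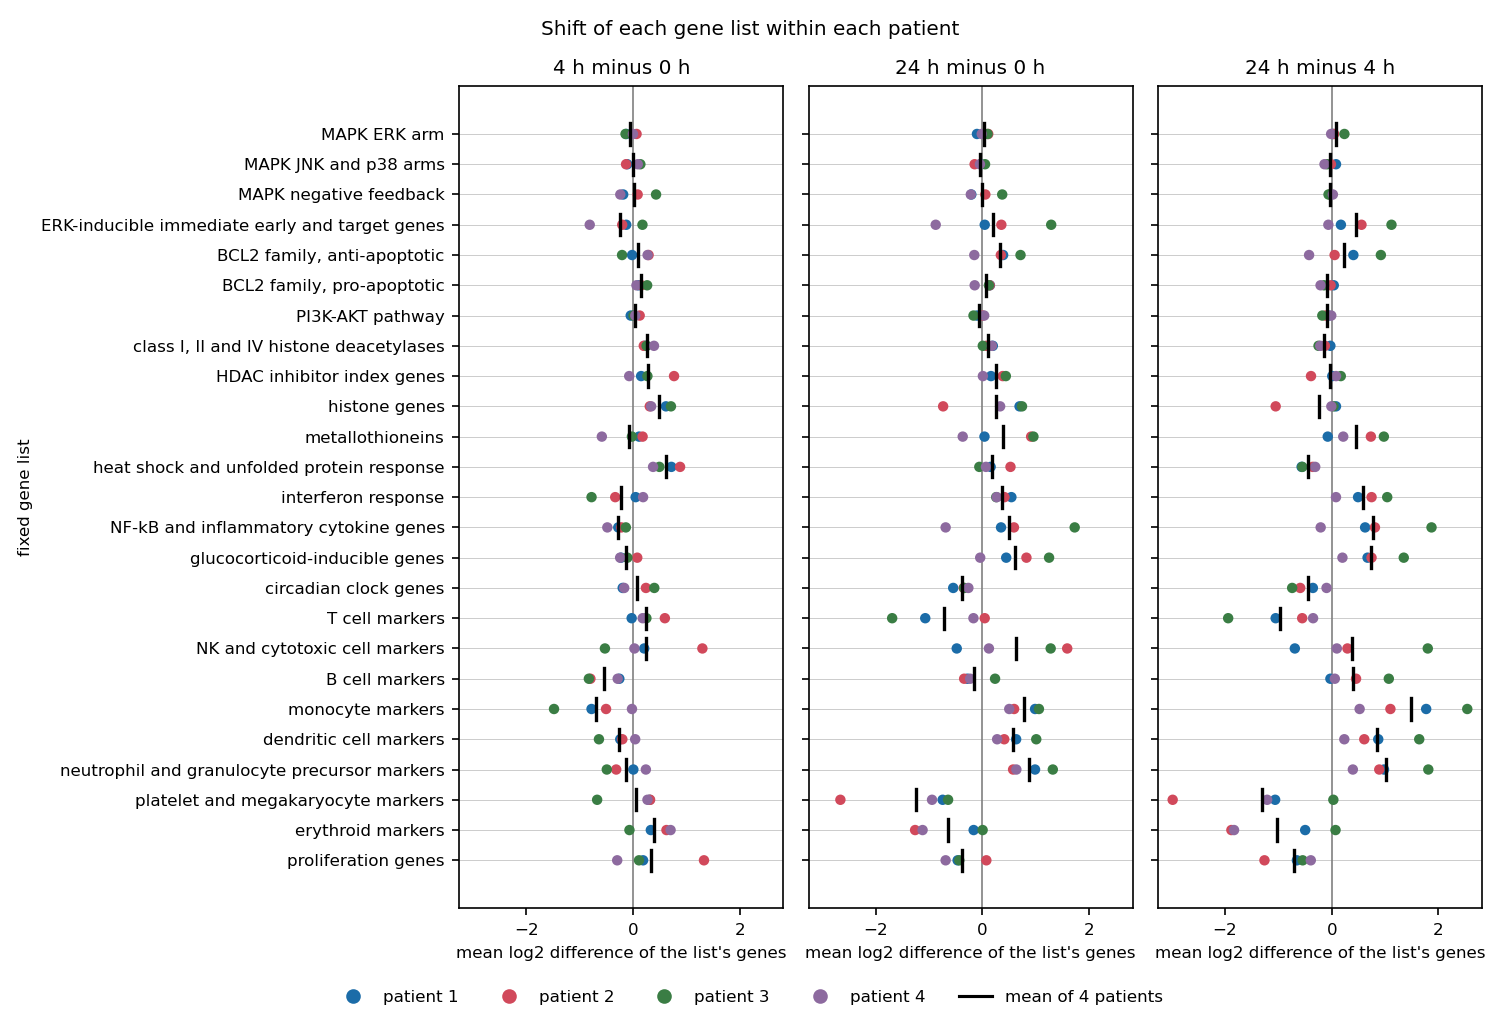
Mean log2 difference (horizontal axis) over the genes of each of 25 lists (vertical axis) in the 3 comparisons (panels), with a dot for each of patients 1 to 4 and a black bar at their mean. Monocyte markers lie at -0.70 for 4 h against 0 h, 0.79 for 24 h against 0 h and 1.48 for 24 h against 4 h, and the ERK arm at -0.05, 0.02 and 0.07.

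The comparisons of 4 h and of 24 h share their 0 h arrays. A total of 25 genes passed in both in the same direction, 16 higher and 9 lower, and 0 in opposite directions. Independent calls would share 3.95. In 50 simulations where the called changes fell on genes drawn independently for each time, with common 0 h arrays, 332 and 94 genes were called and 2.66 shared on average (at most 5). Their noise was drawn independently for each gene and array, without the correlated genes and shared patient deviations of the data. They also called fewer genes than the data did. Their range therefore cannot bound what common 0 h arrays could give here. Simulations with no change gave 0 shared genes, but they called only 0.02 and 0.06 genes on average and so say little. Chosen after their values were seen, examples are EXTL2, an enzyme of heparan sulfate synthesis (2.17 at 4 h and 2.03 at 24 h), the histone H4C14 (2.02 and 2.15), the adhesion receptor ADGRL1 (1.81 and 1.86), TNFAIP6 (1.18 and 1.91) and APAF1, the scaffold of the apoptosome (1.03 and 1.30). When the 0 h arrays were divided between the comparisons, with 2 arrays in each, the count ranged from 0 to 10 over 6 divisions, with a median of 0. Each division sets the 0 h arrays of 2 patients against the later arrays of all 4, which mixes time with differences between patients. It therefore cannot show whether the shared genes come from the common 0 h arrays. The only division with shared genes also had 6 in opposite directions. Calls ranged from 2 to 1095 at 4 h and from 0 to 466 at 24 h. With the block 298 genes were shared, where independent calls would share 101, and 12 were in opposite directions. No simulation with common 0 h arrays was run for that fit, so what they add to its count is not known. The count was 0 in limma's planned fit of 21 arrays, which called no gene and includes 9 arrays with labels in doubt. It was 0 without patient 1 or patient 2, 6 without patient 3 and 3 without patient 4 (EXTL2, H4C14 and JADE2).

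The shift of each list was also compared patient by patient with an exact 2-sided sign-flip test. With 4 patients its smallest p is 0.125, so 0 of 25 lists could pass in any comparison. With the 7 patients of the value table the smallest possible p is 0.0156 before adjustment over 25 lists, so a list can pass only if several others reach it too. The smallest adjusted p was 0.0977 for 4 h against 0 h, and 0.0781 for each of the other comparisons. At 4 h against 0 h the lists at this smallest p included deacetylases, higher in 7 of 7 patients. Monocyte, NF-kB and glucocorticoid-inducible genes, lower in 7 of 7, reached it too.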

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

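The tests of the time labels of patients 5 to 7 were chosen only after the disagreement between the deposited sources was seen. All other tests here were planned.

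The 9 samples of patients 5, 6 and 7 are in no comparison of the main results, yet their values hold a signal. Under the value table's labels, the mean difference of these 3 patients had the sign found in patients 1 to 4 for 95.3% of the 556 genes called at 4 h against 0 h (64.7% of all genes), 98.7% of the 151 called at 24 h against 0 h (72.6%) and 96.4% of the 768 called at 24 h against 4 h (70.8%). Under the scanner labels the shares were 17.4%, 74.2% and 29.6%, against 41.9%, 58.2% and 41.9% of all genes.

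A candidate explanation is that the scanner files of patients 5 and 6 carry labels one time step early. Under the value table's labels, the 4 h minus 0 h differences of these patients correlated across genes with the mean of patients 1 to 4 at 0.612 and 0.728, where patients 1 to 4 had 0.54 to 0.752 with each other's means; genes are not independent replicates. The opposite explanation, that the value table's columns of patients 5 and 6 carry labels one time step late, is argued against by -0.404 in patient 5 under the scanner labels, and less firmly by -0.549 in patient 6, which uses an array with 60.1% of probes above background. The 24 h minus 0 h differences under the scanner labels go partly the other way, with 0.346, -0.222 and 0.266 in patients 5, 6 and 7, and do not argue against late labels in patients 5 and 7. For patient 7 the 4 h minus 0 h values were 0.074 (value table) and 0.0543 (scanner), and both use the array with 50.3% of probes above background. In the comparisons that avoid that array, patient 7 had 0.656 at 24 h against 0 h under the value table's labels (0.469 to 0.707 in patients 1 to 4) and -0.139 at 24 h against 4 h under the scanner labels (0.567 to 0.74), which argues against late labels in the value table and leaves early labels in the scanner files as a candidate. The scanner files labelled 24 h and the columns labelled 0 h have no partner in these patients, which a shift of labels alone leaves open, and no biological explanation was tested.

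Among the named genes, 12 of 231 groups of 4 arrays held a patient far from the other 3, where 11.6 are expected by chance, and they came from patients 1, 2, 3 and 4 in 2, 4, 4 and 2 cases. Values are log2 intensities, followed by the mean of the other 3 patients. At 0 h these were ATF5 (9.91 against 8.75), RPS6KA4 (9.86 against 9.30) and JAM3 (9.16 against 7.94) in patient 2, VSIG4 in patient 3 (6.09 against 4.84), and CD36 (10.3 against 10.8) and DUSP6 (7.73 against 5.97) in patient 1. At 4 h they were MPDU1 in patient 2 (6.06 against 6.67), and PID1 (4.46 against 5.52) and CEBPD (8.81 against 11.1) in patient 3. At 24 h they were CD36 in patient 3 (12.5 against 12), and NAGPA (8.22 against 8.93) and IFI35 (9.17 against 9.88) in patient 4.

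Among the list means, 4 of 75 groups held such a patient, where 3.75 are expected by chance. These were the monocyte mean at 0 h in patient 2 (10.8 against 10.3), the neutrophil mean at 4 h in patient 3 (5.17 against 5.96) and at 24 h in patient 4 (6.34 against 6.93), and the erythroid mean at 24 h in patient 4 (9.11 against 5.21).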

How the results depend on the processing

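Chosen only after the data were seen were the tests on the 21 arrays with the block, on the value table with the block, without patient 7 or for patients 1 to 4, with normexp offset 50, and without each patient in the blocked fit. The fit of the 21 arrays without the block, planned as the main one, became an alternative once the labels were seen to disagree. Counts are given as genes higher and genes lower for 4 h against 0 h, 24 h against 0 h and 24 h against 4 h, whose main values were 293 and 263, 118 and 33, and 484 and 284, with 25 genes shared by the first 2 comparisons and 3, 6 and 11 lists past camera. Where no construction shows the cause of a change below, the cause was not tested.

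With the patient as a block (the replicate block) the counts were 994 and 890, 649 and 516, and 1246 and 1133, with 298 shared genes and 11 lists at 24 h against 0 h. All genes called without the block were called with it, and it changed no call of a named gene or list beyond those given in the results. With a random replicate block (consensus correlation 0.411) they were 1009 and 927, 727 and 543, and 1275 and 1066, with 347 shared. Of the called named genes 12 of 30, 5 of 23 and 22 of 38 still passed in the value table of 7 patients, 28, 23 and 35 with the block, and 28, 16 and 37 after scaling to the 75th percentile (lost there were also TNFAIP6 at 4 h and GADD45A). The labels of patients 5 to 7 are in doubt in the value table too. The value table of 7 patients gave 116 and 104, 14 and 1 (CTTN), and 184 and 94, with 1 shared gene (NABP1), and 0.392 for ERK-inducible genes at 24 h against 4 h (adjusted p = 0.0321). With the block it gave 757 and 903, 439 and 278, and 1148 and 906, with 181 shared and 11 lists at 24 h against 0 h. Without patient 7 the table gave 194 and 126, 24 and 9, and 183 and 136, with 4 shared (APAF1, BUD23, JADE2 and NABP1) and 0.458 for ERK-inducible genes (adjusted p = 0.00663). Scaling to the 75th percentile turned the balance at 4 h to 231 and 277 (977 and 1482 at an unadjusted p under 0.05, against 1231 and 1145), gave 59 and 24 at 24 h against 0 h (887 and 982, against 1098 and 864) and moved the median of all genes from -0.01 to -0.13 at 4 h, from -0.03 to -0.11 at 24 h against 0 h and from -0.02 to 0.0067 at 24 h against 4 h. With only the arrays of the 2 times compared, 12 and 6 genes passed at 4 h against 0 h (947 and 852 at an unadjusted p under 0.05), with 3 shared (EXTL2, HSPA1B and NABP1). That fit has fewer samples, but it gave higher counts in the other comparisons. They were 165 and 40 at 24 h against 0 h and 510 and 353 at 24 h against 4 h. The cause of the drop at 4 h was not tested.

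The monocyte marker mean itself moved with time, so as a covariate it takes up part of the time differences, and lost calls do not show their cause. With it as a covariate limma called 30 and 27, 0 and 0, and 0 and 0 genes (804 and 809, 809 and 598, and 405 and 369 at an unadjusted p under 0.05), with 0 shared. Of the other lists past camera it kept 2 of 2, 1 of 5 and 1 of 10, only the platelet list in the comparisons of 24 h, and called 1 new list at 4 h against 0 h and 2 at 24 h against 4 h, so that 1 list passed at 24 h against 0 h and 3 at 24 h against 4 h. At 24 h against 4 h CD1D reversed to -0.0291 and 80 of the 768 called genes changed sign. All 21 arrays under the scanner labels, which are in doubt for 9 of them, gave 0 in all 6 counts and 0 shared genes in limma (118 and 66, 402 and 231, and 81 and 104 at an unadjusted p under 0.05). With the block they also gave 0 in all 6 counts and 0 shared (365 and 246, 825 and 659, and 283 and 295). They gave 6, 6 and 9 lists (7, 10 and 12 with the block), among them 2 of 3, 5 of 6 and 8 of 11 of those reported (2, 6 and 8 with the block). Lost at 24 h against 4 h in both were the NF-kB, glucocorticoid and clock lists, and at 24 h against 0 h without the block interferon genes (adjusted p = 0.0634). Reversed at 4 h against 0 h under these labels were glucocorticoid-inducible genes (0.315), monocyte markers (0.271) and platelet markers (-0.412), neutrophil markers with the block (0.241), CD14 (0.11) and MS4A6A (0.267). With an estimated correlation, camera called 0, 0 and 0 lists in the main fit, the only one run that way. With the 0 h arrays divided between the comparisons, which mixes time with differences between patients, a median of 0 genes was shared. The calls ranged from 2 to 1095 and from 0 to 466, with 2 arrays at 0 h in each comparison.

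Leaving out 1 patient, which takes samples away, gave 0 to 146 higher and 0 to 107 lower at 4 h against 0 h, 0 to 29 and 0 to 8 at 24 h against 0 h, and 0 to 495 and 0 to 273 at 24 h against 4 h. In the fit with the replicate block the ranges were 117 to 984 and 69 to 853, 8 to 728 and 0 to 476, and 336 to 1161 and 253 to 992. In both fits the lowest of each count was that without patient 1 and the highest that without patient 3 or 4. In the fit without the block, leaving out patient 2 gave the same lowest count of 0 for genes lower at 4 h against 0 h and in both directions at 24 h against 0 h. In the fit with the block, 753 and 550 genes passed at 24 h against 4 h without patient 2, 545 passed as lower there without patient 3, and 759 and 713 passed at 4 h and 316 and 208 at 24 h against 0 h without patient 4. Shared genes ranged from 0 to 6, and from 3 to 463 with the block (82 without patient 4, and EPHA1, EXTL2 and NABP1 without patient 1). Lists past camera ranged from 1 to 4, 5 to 9 and 10 to 13, and with the block from 3 to 6, 8 to 13 and 12 to 16. The mean of ERK-inducible genes ranged from -0.158 to 0.565 at 24 h against 0 h and from 0.222 to 0.615 at 24 h against 4 h, with 0.537 without patient 1. In both comparisons the lowest was that without patient 3 and the highest that without patient 4. Every called gene kept its sign in each of these fits without a block.

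Without background correction, with normexp offset 50, with mean probes, without the variance trend, with no filter or a stricter one and in the value table of patients 1 to 4, all gene counts stayed within 1.5 times the main values. Under the stricter filter the glucocorticoid, neutrophil and platelet lists no longer passed at 24 h against 0 h, nor did the glucocorticoid, clock and platelet lists at 24 h against 4 h; fewer genes (8273) were tested. In the value table of 7 patients histone genes at 4 h (0.281, adjusted p = 0.0583), interferon genes at 24 h against 0 h (0.238, adjusted p = 0.0602) and clock genes at 24 h against 4 h (adjusted p = 0.113) no longer passed. Nor did these 3 without patient 7, the histone and clock lists with the block on that table, or interferon genes in the table of patients 1 to 4 (0.306, adjusted p = 0.0531). The patient-wise list shifts passed in 0 lists in every setting run, and the sign-flip test on 4 patients or fewer could not pass in any. Signal over background limits genes near the floor, such as SPRED2. Not run were a block for the chip or slide, camera with the random block, and the monocyte list under its own covariate. In each comparison and direction, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many genes: the highest other count in 1 direction was 133 at 4 h against 0 h, from a split that keeps pairs together, and 0 for the other comparisons. Most of these splits break the pairing of arrays by patient. The 8 splits that part all 4 pairs are too few for a share under 0.05, and their highest other count was 0 in each comparison.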

Other observations

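The tests of the time labels that bear on patients 5 to 7 were chosen only after the disagreement was seen; the tests of the marker lists were planned.

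Under the value table's labels the lists moved in patients 5, 6 and 7 by the following mean log2 differences, which enter no test. Monocyte markers had -0.716 at 4 h against 0 h, 0.675 at 24 h against 0 h and 1.39 at 24 h against 4 h. Heat shock genes had 0.245, 0.0622 and -0.183, and glucocorticoid-inducible genes -0.349, 0.446 and 0.795. T cell markers had 0.189, -0.43 and -0.619, and platelet markers -0.074, -0.959 and -0.885. The ERK arm had -0.0323, 0.0106 and 0.0429, and ERK-inducible genes -0.221, 0.196 and 0.417. Under the scanner labels monocyte markers had 1.55, 1.17 and -0.379, and the ERK arm 0.0438, 0.0492 and 0.0054.

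Of the 25 genes called in the same direction at 4 h and at 24 h against 0 h, those not given with their values were ARMCX2, FAM89A, IDH1, ITPR1, LYSMD2, NABP1, NMRK1, PLA2G4A, SPTSSA, STK38L and UBA3, which were higher, and ANKRD39, BUD23, JADE1, JADE2, LMTK2, NDUFS3, SLC30A5, ZFAND2A and ZNF507, which were lower. They include IDH1, a cytosolic dehydrogenase that makes NADPH, PLA2G4A, the phospholipase that releases arachidonic acid, ITPR1, a calcium channel of the endoplasmic reticulum, and JADE1 and JADE2, subunits of histone acetyltransferase complexes. All were chosen after their values were seen.

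Monocyte and platelet markers moved with time, and a change in the number of cells could do that. Fewer monocytes at 4 h with unchanged expression per cell would shift all markers alike if no other cell expressed them and all signals exceeded background. At 4 h 6 of 17 departed from the list's own shift, with CD14 at -1.01 and KLF4, which other cells express too, at 1.41. From 4 h to 24 h 9 of 17 departed, such as CD14 (0.87) and FCN1 (-0.68). From 0 h to 24 h 10 of 15 platelet markers did, among them GP9 (-2.35), CTTN and F13A1 (2.90), which monocytes also express. At 24 h GP9 was above background on 3 of 4 arrays and CTTN on 2 of 4. Such members also move the mean from which departures are measured. The departures therefore cannot decide whether cell numbers changed. A change in cell numbers stays open, as the whole or a partial cause, beside a change in expression, since no cell counts are used here. The effect of romidepsin over time is the biological explanation in the design, and it was not tested against these.

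Glucocorticoid-inducible genes were higher at 24 h than at 0 h, for which more monocytes or glucocorticoid exposure could account. The 10 members that lymphocytes express too had a mean shift of 0.109 (SD 0.705, 2 of 4 patients higher), and the other 5 members, such as VSIG4 and CD163, one of 1.64 (SD 0.405, 4 of 4). The spread of the first value covers what each explanation predicts, so more monocytes in the 24 h samples and glucocorticoid exposure between 0 h and 24 h cannot be told apart. At 24 h against 4 h the means were 0.156 and 1.92.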
